A study of Homo sapiens with 9 samples.

How the data were processed

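RNA from 9 prostate cultures was hybridised by the authors to Affymetrix HG-U133 A arrays, 1 array per culture. Per the labels, total RNA was extracted with a Qiagen RNeasy kit and labelled with biotin, and no culture was treated. Per the submitters' processing notes, signals were made with MAS5; its version and settings are not given in the sources used here. The deposited values are intensities on a linear scale, never negative, for 22283 probe sets. The trimmed mean, with 2% of probe sets removed at each end, came to the same value on every array, so the authors' scaling was kept. Detection calls were not used here.

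Samples were grouped from the labels as 6 cancer lines, 1 normal epithelial culture and 2 normal stromal cultures. Replicate numbers followed accession order and pair nothing. GAPDH 3' to 5' ratios ran from 0.787 to 1.00 and actin ratios from 0.839 to 1.19. The mean log2 signal of the spike-in control probe sets ran from 9.16 in LAPC4 to 9.90 in C42B. No batch was named in the labels. Medium goes with the stromal group and cannot be separated from it.

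Probe sets were named from a table of the platform's probe sets and genes, with symbols updated by Entrez identifier against the GRCh38.p14 RefSeq gene table, which was used for names alone; 11954 of 11964 identifiers matched. Of the probe sets, 19071 had 1 symbol, 1043 several and 2169 none in the table used here. For each of 11939 genes with a probe set, the probe set with the highest mean was taken, and sets marked as cross-hybridising (_x_at) were used only where a gene had no other. A gene was kept where its signal exceeded the array's own median on at least 1 array, which left 9364 genes, 349 of them on such sets. Among the kept genes were KRT8, KRT18, MAGEA1, MAGEA6, MAGEA12 and CXCL2 on cross-hybridising sets. AMACR and ERG were not kept. Of 497 genes in 21 fixed lists, 437 had a named probe set; the others and a few named in the fixed rule are not reported here. Genes of the sex chromosomes that identify a donor's sex were left out. Of the 68 named genes called against stroma, 31 had several probe sets, all of the same sign in 26. In the other 5 (PDGFRA, CD44, ACTA2, DKK3 and COL3A1) at least 1 probe set had the opposite sign, none of them called.

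Values were analysed as log2(signal + 18), where 18 is the rounded median over arrays of the 25th percentile. Differences are on this scale, which understates the change of dim genes. Where the dimmer group lay below the array median on all its arrays, the change of a gene that passed is also given as "at least N-fold". That bound sets the brighter group's mean log2 signal against the mean over the dimmer group's arrays of the higher of the array's median and the gene's signal. Group means were fitted with limma (version 3.58.1, R 4.3.3), with lmFit on all 9 arrays and eBayes with a variance trend. Tests were two-sided with Benjamini-Hochberg adjustment over the genes kept, and a gene was called at an adjusted p under 0.05. The comparison with all 3 normal cultures used 2 groups. PC-3 and DU-145 were set against the other 4 lines within the 6 lines. Errors after ± are standard errors from limma.

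Gene lists were tested with camera at an inter-gene correlation of 0.01 over the 20 lists with at least 5 genes kept, with the correlation also estimated per list, and with fry. Fry passed 11, 5 and 6 lists for the lines against stroma, the lines against PrEC and PrEC against stroma, where camera passed 14, 10 and 7. The lists were androgen response, luminal, junction, basal, matrix, mesenchymal, contractile, cell cycle, interferon, class I antigen presentation, sterol, fatty acid, hypoxia and glycolysis, oxidative phosphorylation, NF-kappaB, genes often silenced or often raised in prostate cancer, cancer-testis antigens, neuroendocrine, endothelial and leukocyte markers. Named genes followed a rule fixed before the data were examined. It takes the 10 largest differences each way per comparison (5 for the 2 smaller ones), among called genes whose groups do not overlap, and up to 4 called genes per list. It adds 3 genes per line and a fixed set of prostate, epithelial, mesenchymal and cancer genes, named with their values whether or not they passed.

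The fit was tested on simulated data with the real mean and within-group spread of each of 9364 genes, 200 of them changed, in 20 draws. For the lines against stroma, 61.7% of genes changed by 2 on the log2 scale and 92.7% of those changed by 4 were recovered. Against PrEC these shares were 36.0% and 81.4%, and for PrEC against stroma 24.8% and 77.2%. For the lines against all 3 normal cultures they were 74.8% and 96.2%, but the simulated normal cultures held no difference between PrEC and stroma. That difference adds to the real spread, so these 2 shares are not to be expected of the real comparison. For PC-3 and DU-145 against the other lines the shares were 48.2% and 89.4%. Between 4.04% and 5.52% of the calls were false. The arrays were drawn independently with 1 spread per gene for all groups, as limma assumes, so this share was largely set in advance. It does not cover related lines such as LNCaP and C42B, or a spread of PrEC or stroma unlike that of the lines. A list shifted by 1.5 was found by camera in 20 of 20 draws for each of the first 3 comparisons. There were 6, 5 and 4 calls among 380 tests of unshifted lists. The simulated genes were drawn independently, so these rates do not hold for lists of correlated genes. For the lines against stroma, the estimated correlation was 0.0034 for the contractile list and 0.64 for the cell cycle list. Alternatives were quantile normalization, median centring, pseudocounts of 1 and 60, no filter and a filter on the mean, the mean of a gene's probe sets, no variance trend, LNCaP and C42B averaged, only the 2 groups compared, R1881 as a covariate, an estimated inter-gene correlation, and each sample left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.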

Results

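Expression was measured on 9 Affymetrix HG-U133 A arrays, 1 for each of 9 untreated human prostate cultures. The 6 cancer lines were LNCaP, C42B, LAPC4, CWR22Rv1, DU-145 and PC-3, all established lines. C42B was derived from LNCaP, so these 2 lines are related and not independent samples. The normal cells were 1 primary epithelial culture (PrEC) and 2 primary stromal cultures, called stromal culture 1 and stromal culture 2. The labels give RPMI medium for the lines and PrEC, and Iscove's medium for the stromal cultures, each with 10% serum. R1881, a synthetic androgen, was present at 1 nM in both stromal cultures and in LAPC4. The authors' MAS5 signals had a trimmed mean of 150.04 to 150.06 on every array and a median of 57.7 to 70.8. The number of arrays limits the precision: each culture was measured on 1 array, so p-values rest on the spread between different lines or cultures and not on repeated measurement of any of them.

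Across the 9364 genes kept, arrays of related cells resembled each other most. The correlation across genes was 0.92 between LNCaP and C42B and 0.93 between the stromal cultures, where genes are not independent replicates. DU-145 and PC-3 correlated with PrEC at 0.81 and 0.79, and the other 4 lines at 0.68 to 0.73. PrEC correlated with the stromal cultures at 0.74 and 0.71, about as much as with those 4 lines. Correlations of the lines with the stromal cultures ran from 0.59 to 0.70.

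**Figure D1:**
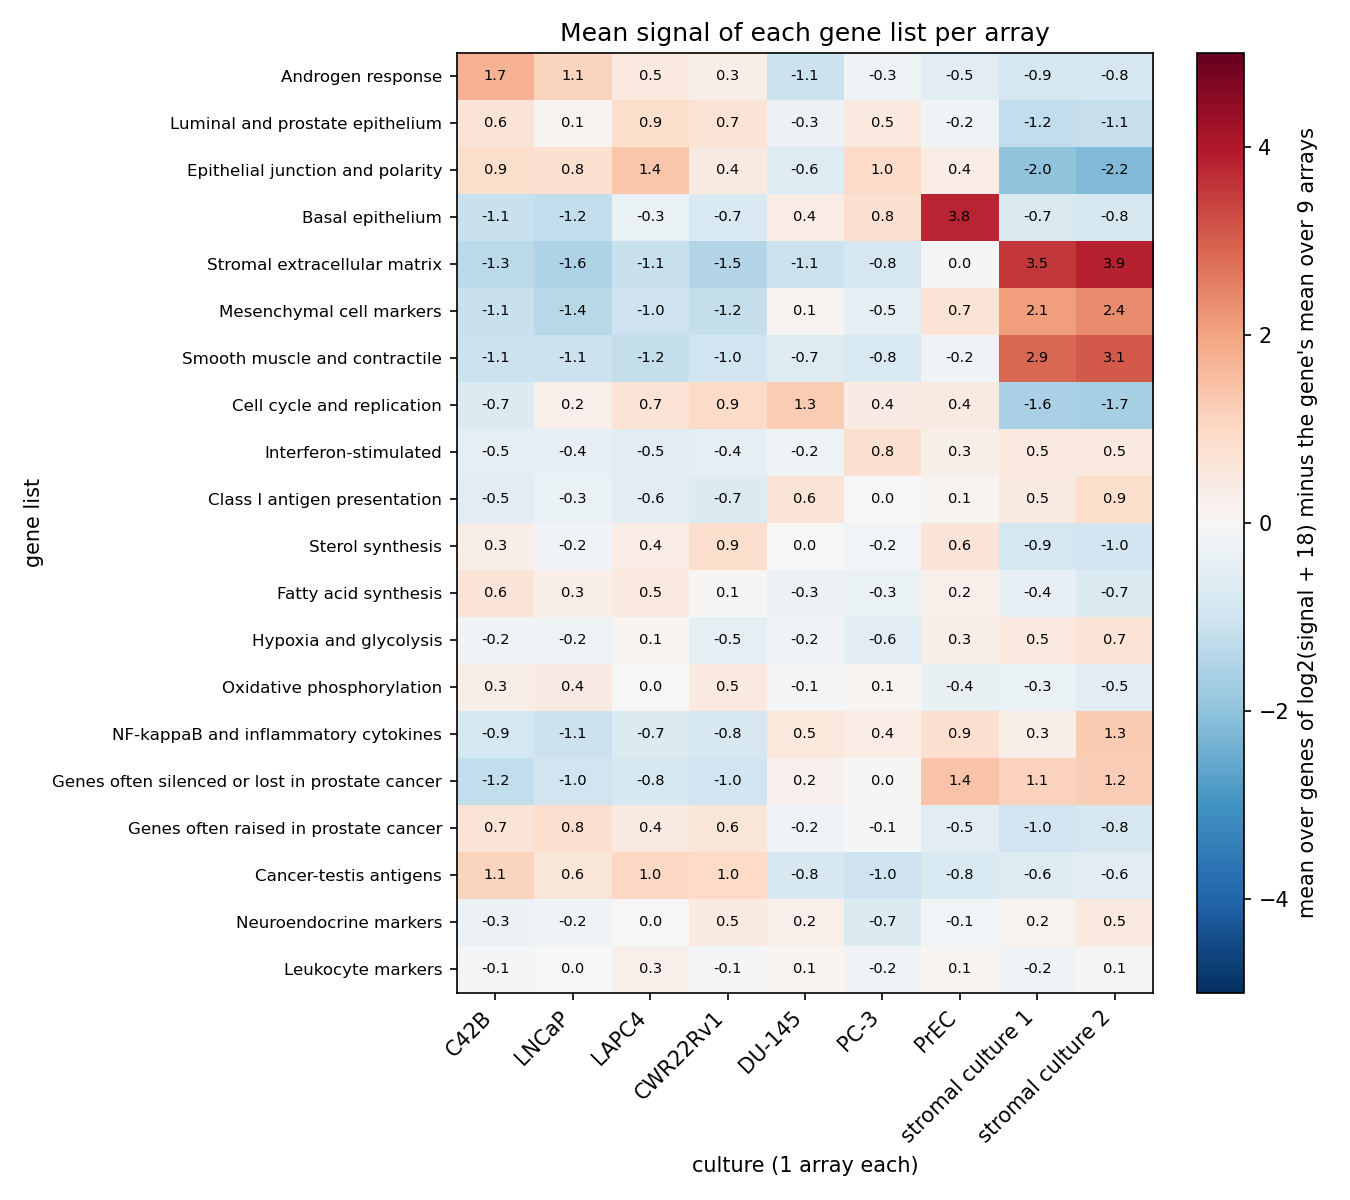
Mean signal of each of 20 gene lists (rows) on each of the 9 arrays (columns, 1 array per culture), as the mean over the list's genes of log2(signal + 18) minus that gene's mean over the 9 arrays; red is above and blue below the mean. The stromal extracellular matrix list stands at 3.54 and 3.86 in the stromal cultures and below 0 elsewhere, and the basal epithelium list at 3.80 in PrEC.

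The first comparison asked how the 6 cancer lines differ from normal stromal cells. The lines had lower signals for most listed genes of the matrix, the contractile apparatus and mesenchymal cells. They had higher signals for 12 of 20 genes of epithelial adhesion and 21 of 32 of the cell cycle, 2 lists with an adjusted p of 0.139 and 0.228 with an estimated correlation. CDH1, which encodes E-cadherin, was higher in the lines by 5.69 ± 0.74 on the log2 scale (SE, n = 6 lines and 2 cultures). The change was at least 19.2-fold, with an adjusted p of 0.00108 in limma. That bound is for the mean of the lines, and DU-145 had a signal of 200 against 1100 to 2110 in the other lines. COL1A1, a chain of type I collagen, differed by −8.40 ± 0.39 (SE), at least 165-fold lower in the lines, with an adjusted p of 7.5e-07. In all, 1201 of 9364 genes passed an adjusted p of 0.05 in limma, 621 higher and 580 lower in the lines. Which direction held more genes depended on the setting: the split was 529 and 598 with quantile normalization, 485 and 609 with median centring, 115 and 227 without stromal culture 1 and 74 and 172 without stromal culture 2. The median difference over all genes was 0.16.

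The genes with the largest increases over stroma included several of epithelial junctions and surfaces. The protease inhibitors SPINT2 and SPINT1 were higher by 4.55 ± 0.39 and 3.94 ± 0.38, at least 19.0-fold and 5.79-fold. The tight junction genes CLDN3 and CLDN7 were higher by 4.32 ± 0.54 (at least 6.55-fold) and 4.23 ± 0.60 (at least 14.6-fold), the desmosomal cadherin DSG2 by 4.19 ± 0.64 (at least 10.2-fold), and the adhesion molecule EPCAM by 4.18 ± 0.42 (at least 13-fold). EEF1A2, a translation elongation factor, was higher by 4.16 ± 0.94, and the centromere protein gene CENPN by 4.10 ± 0.82 (at least 6.21-fold). Adjusted p over these 8 genes ran from 7.79e-05 for SPINT2 to 0.0182 for EEF1A2. Of the 20 epithelial junction and polarity genes measured, 12 were higher in the lines and 0 lower, or 17 when adjusted over the list alone. DU-145 stood apart, with a list mean of −0.63, against 0.43 to 1.39 in the other 5 lines and −2.00 and −2.20 in stroma. The list's median difference was 2.29, with a camera adjusted p of 2.07e-11, and an adjusted p of 0.139 with an estimated correlation.

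Many proliferation genes rose, least in C42B. Of 32 cell cycle and replication genes, 21 were higher in the lines and 0 lower, or 27 adjusted over the list alone. The list mean was −0.70 in C42B, against 0.24 to 1.27 in the other 5 lines and −1.63 and −1.68 in stroma. The mitotic kinase gene CDK1 was higher by 4.29 ± 0.57 (at least 10.4-fold), TOP2A, encoding a topoisomerase, by 3.45 ± 0.75 (at least 4.35-fold), the replication helicase gene MCM7 by 3.31 ± 0.54 (at least 7-fold), and BIRC5 (survivin) by 3.23 ± 0.62 (at least 4.77-fold). MKI67, the Ki-67 antigen, differed by 0.70 ± 0.36 and did not pass (adjusted p = 0.247). The list's median was 2.18, with a camera adjusted p of 1.01e-12, and an adjusted p of 0.228 with an estimated correlation.

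Matrix and contractile genes showed the largest decreases. Of 29 stromal extracellular matrix genes, 27 were lower in the lines, or all 29 adjusted over the list alone, with a median of −5.18. COL3A1 differed by −7.82 ± 0.36, at least 102-fold lower, the matrix protein gene SPARC by −7.66 ± 0.28 (at least 80.1-fold), COL1A2 by −7.52 ± 0.27 and COL6A3 by −6.92 ± 0.49. Of 18 smooth muscle and contractile genes, 12 were lower, or 16 adjusted over the list alone. Among them were TPM2, a tropomyosin, at −7.46 ± 0.26 (at least 61-fold), the myosin light chain gene MYL9 at −7.17 ± 0.86, TAGLN at −6.96 ± 0.30 (at least 121-fold) and the smooth muscle actin gene ACTA2 at −5.69 ± 0.24. Of 20 mesenchymal markers, 15 were lower, or 18 adjusted over the list alone, including TGFBI at −7.46 ± 0.85, VIM at −4.54 ± 1.18, FAP at −4.53 ± 0.33 (at least 11.7-fold) and the growth factor receptor gene PDGFRA at −4.48 ± 0.34 (at least 7.32-fold). DU-145 stood apart on this list, with a mean of 0.12 against −0.50 to −1.39 in the other 5 lines, and its VIM of 12.25 was near 12.68 and 13.13 in stroma. ZEB1, a repressor of epithelial genes, stood at −4.11 ± 0.58. The camera adjusted p was 9.94e-39 for the matrix list, 2.93e-22 for the contractile list and 4.51e-16 for the mesenchymal list. With an estimated correlation, the adjusted p was 0.000841, 0.000841 and 0.00832, and these 3 were the lists that passed that way out of 20. Outside these lists, IGFBP7, an insulin-like growth factor binding protein gene, was lower by at least 49.1-fold, at −6.61 ± 0.40.

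Some inflammatory, interferon and hypoxia genes were lower in the lines, but 3 list means did not lie below both stromal cultures in every line. The NF-kappaB list, centred on its mean over the 9 arrays, stood at 0.54 in DU-145 and 0.38 in PC-3, against 0.35 and 1.31 in the stromal cultures and −0.68 or less in the other 4 lines. The interferon list stood at 0.79 in PC-3, above 0.49 and 0.47 in the stromal cultures, and the class I list at 0.63 in DU-145, between 0.47 and 0.89 in stroma. Of 22 NF-kappaB and cytokine genes, 6 were lower in the lines, also 6 adjusted over the list alone, among them the chemokine genes CCL2 at −5.58 ± 0.32 (at least 18.7-fold), CXCL6 at −3.23 ± 0.56 and CXCL1 at −3.13 ± 0.87, and IL6 at −2.92 ± 0.57. CXCL8 differed by −2.19 ± 1.31 and did not pass (adjusted p = 0.321). Of 31 interferon-stimulated genes, 7 were lower and 2 higher, or 9 and 2 adjusted over the list alone. TRIM22 stood at −3.85 ± 0.32 (at least 7.31-fold), GBP1 at −3.09 ± 0.38 (at least 3.12-fold), GBP2 at −2.45 ± 0.37 (at least 4.52-fold) and IFITM2 at −2.18 ± 0.62. Of 27 hypoxia and glycolysis genes, 6 were lower, also 6 adjusted over the list alone, including ADM (adrenomedullin) at −4.89 ± 0.58, P4HA1 at −1.70 ± 0.32, CA12 at −1.58 ± 0.44 and the glucose transporter gene SLC2A3 at −1.57 ± 0.36 (at least 1.61-fold). Of 16 class I antigen presentation genes, 1 was lower, B2M at −1.66 ± 0.47, and it did not pass when adjusted over the list alone. Camera adjusted p for these 4 lists was 1e-04, 0.0015, 3.48e-05 and 0.00131. With an estimated correlation the adjusted p was 0.346, 0.359, 0.139 and 0.218.

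Some lipid and respiratory genes were higher in the lines than in stroma. Of 18 sterol synthesis genes, 4 were higher, or 11 adjusted over the list alone. TM7SF2 rose by 3.29 ± 0.68 (at least 6.47-fold), EBP by 2.05 ± 0.42, HMGCS1 by 2.01 ± 0.46 and HSD17B7 by 1.81 ± 0.34. Of 14 fatty acid synthesis genes, 3 were higher, also 3 adjusted over the list alone, among them the desaturase gene SCD by 2.68 ± 0.37, the carboxylase gene ACACA by 2.36 ± 0.60 and TECR by 1.74 ± 0.37. That list had a camera adjusted p of 0.15 and did not pass. Of 35 oxidative phosphorylation genes, 4 were higher, or 5 adjusted over the list alone, CYC1 by 1.94 ± 0.36, NDUFV1 by 1.33 ± 0.28, NDUFV2 by 1.09 ± 0.30 and ATP5PO by 0.90 ± 0.26. Camera adjusted p was 0.000217 for sterol synthesis and 0.000437 for oxidative phosphorylation. With an estimated correlation the adjusted p was 0.276 and 0.327.

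Prostate and tumour gene lists were mixed. Of 15 luminal and prostate epithelial genes, 2 were higher in the lines, also 2 adjusted over the list alone, the transcription factor gene FOXA1 by 3.11 ± 0.55 (at least 7.73-fold) and the keratin gene KRT8 by 2.30 ± 0.49. KRT8 and KRT18 were read from probe sets that can cross-hybridise, so their values are uncertain. Of 17 genes often raised in prostate cancer, 4 were higher, or 4 and 1 lower adjusted over the list alone, TPD52 by 3.89 ± 0.43 (at least 16.3-fold), HOXC6 by 2.17 ± 0.42 (at least 3.8-fold), EZH2 by 2.08 ± 0.49 (at least 1.32-fold) and MYC by 1.98 ± 0.46. Of 26 genes often silenced or lost, 8 were lower, or 13 adjusted over the list alone, led by DKK3 at −6.53 ± 0.55, CAV1 at −5.05 ± 1.30, RARRES1 at −4.01 ± 0.58 (at least 6.95-fold) and the cell cycle inhibitor gene CDKN1A at −3.23 ± 0.72. DU-145 and PC-3 stood apart on that list, with means of 0.20 and 0.04 against −0.82 to −1.24 in the other 4 lines. Camera adjusted p for these 3 lists was 0.0106, 0.00727 and 5.89e-07. With an estimated correlation the adjusted p was 0.139, 0.19 and 0.139. Of 17 androgen-response genes, 1 was higher, TPD52, which also stands in the raised list. R1881 was in both stromal cultures and, among the lines, in LAPC4 alone, so androgen in the medium differed as well. This list did not pass, with a camera adjusted p of 0.148. The remaining lists did not pass either. Camera adjusted p was 0.622 for 20 basal epithelial genes, where CD44 was lower at −4.73 ± 1.20 and JAG2 higher by 1.46 ± 0.35. It was 0.845 for 12 genes listed as cancer-testis antigens, where MAGED1 was lower at −2.04 ± 0.32, the list's median of 0.89 having the opposite sign. MAGED1 had a mean signal of 671 in the lines and 2730 in stroma, so it was not restricted to cancer cells here. For neuroendocrine and leukocyte markers camera did not pass either. Camera adjusted p was 0.233 for 12 neuroendocrine markers, where UCHL1 was lower at −5.02 ± 1.35 and SCG5 at −1.77 ± 0.48. For 9 leukocyte markers it was 0.937, with 0 genes called and a median of 0.15 where the test pointed down. Of the endothelial list 3 genes were kept, too few to test. PECAM1, VWF and TEK had adjusted p of 0.63, 0.916 and 0.0915.

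Secretory prostate genes varied widely between the lines. KLK3, encoding prostate-specific antigen, had a signal of 9560 in C42B, 8080 in LNCaP, 2240 in LAPC4, 164 in CWR22Rv1, 8.87 in PC-3 and 5.61 in DU-145. In the stromal cultures its mean was 7.18, and the difference of 4.38 ± 2.28 did not pass (adjusted p = 0.251). KLK2 at 2.48 ± 1.51, TMPRSS2 at 3.97 ± 1.73, HOXB13 at 3.45 ± 1.17 and FOLH1, encoding prostate-specific membrane antigen, at 1.72 ± 0.73 did not pass either, with adjusted p of 0.329, 0.171, 0.0827 and 0.158. GSTP1, a glutathione transferase gene, had signals of 1070 in LAPC4, 575 in PC-3, 284 in DU-145 and 85.2 to 107 in the other 3 lines, against a stromal mean of 1230. Its difference of −2.29 ± 0.85 did not pass (adjusted p = 0.112). RB1 at −0.29 ± 0.53, CDKN2A at −0.11 ± 0.62, ETV1 at 0.20 ± 0.61 and KRT18 at 0.65 ± 0.41 had adjusted p of 0.777, 0.938, 0.871 and 0.349. The basal keratin genes KRT5 at 0.68 ± 0.54 and KRT14 at 0.01 ± 0.36 had 0.461 and 0.989.

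**Figure D2:**
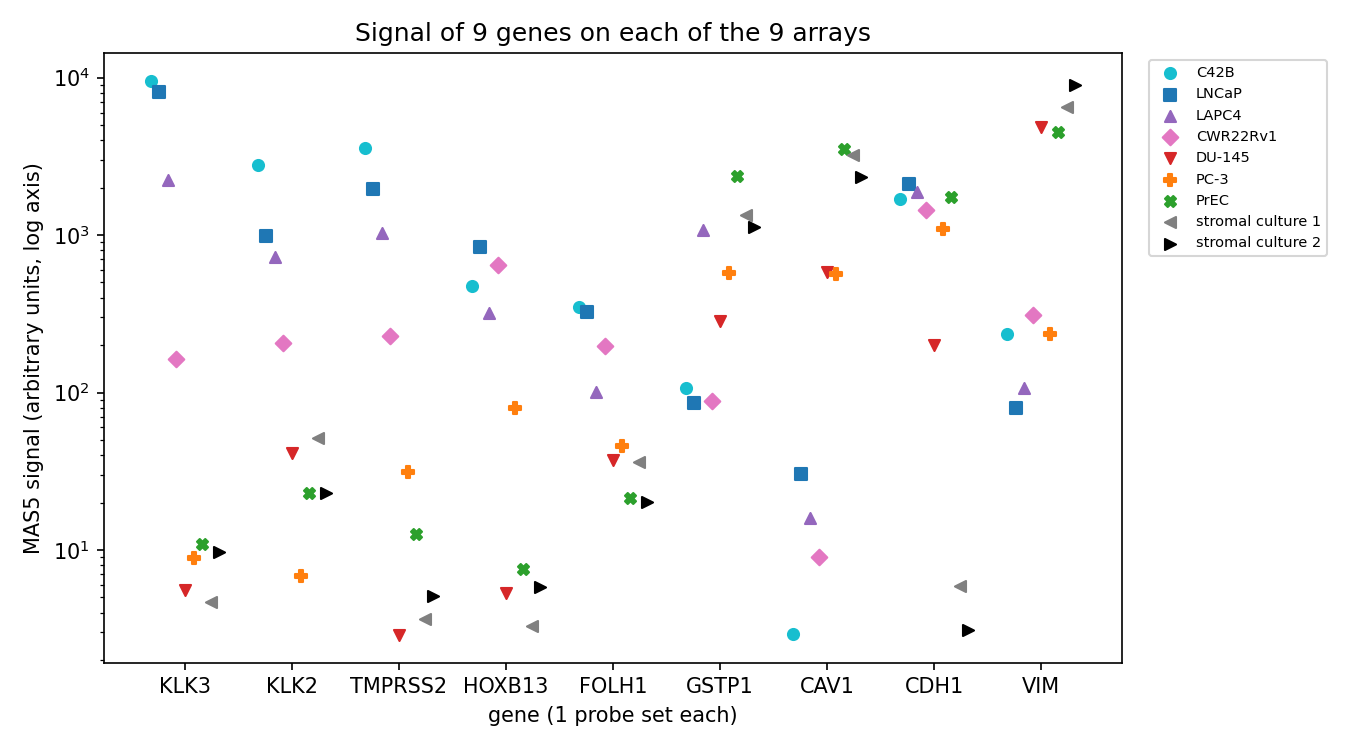
MAS5 signal (vertical log axis, arbitrary units) of 9 genes (horizontal axis), with 1 symbol per array. KLK3 lies at 8080 and 9560 in LNCaP and C42B and at 5.61 and 8.87 in DU-145 and PC-3, CAV1 at 579 and 569 in DU-145 and PC-3 and at 2.94 to 30.5 in the other 4 lines.

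The comparison with stroma rested on 2 stromal cultures. Without stromal culture 1 or stromal culture 2, 342 or 246 genes passed, the remaining culture being assumed to vary like the other groups, and with R1881 as a covariate, an estimate resting on LAPC4, 284 passed. Of the 68 called genes chosen by the fixed rule, 31 lost their call without stromal culture 1, 40 without stromal culture 2 and 34 with the covariate, and 0 changed sign. The rule took called genes with large differences, which leaves a change of sign little room. With the related lines LNCaP and C42B averaged, 9 of the 68 lost their call. The filter on the mean retained 53 of the 68. The 27 that kept their call under every alternative that retained them include CDH1, EPCAM, CLDN3, CDK1, SPINT1, SPINT2, TPD52, COL1A1, COL3A1, SPARC, ACTA2, TAGLN, TPM2, TGFBI, CCL2, ADM and DKK3.

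The second comparison set the 6 lines against PrEC, the normal epithelial culture. Some basal epithelial genes were lower in the lines, 7 of 20, and the list had an adjusted p of 0.0539 with an estimated correlation. Its mean was 0.79 in PC-3 and 0.37 in DU-145, −0.34 to −1.23 in the other 4 lines and 3.80 in PrEC. KRT14 differed by −8.85 ± 0.48 on the log2 scale (SE, n = 6 lines and 1 culture), at least 180-fold lower, with an adjusted p of 3.57e-05 in limma. KRT5 differed by −7.73 ± 0.71, at least 155-fold lower, with an adjusted p of 0.00121. In all, 48 of 9364 genes passed, 6 higher and 42 lower in the lines, and 967 had an unadjusted p under 0.05. PrEC was a single sample and was assumed to vary like the other groups.

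Of 20 basal epithelial genes, 7 were lower in the lines, or 18 adjusted over the list alone, with a median of −3.94. They included FGFBP1, a binding protein of fibroblast growth factor, at −5.96 ± 0.83, and SERPINB5 (maspin) at −5.58 ± 0.97. Camera gave an adjusted p of 5.01e-25, and an adjusted p of 0.0539 with an estimated correlation. Of 22 NF-kappaB and cytokine genes, 3 were lower, the interleukin gene IL1A at −5.59 ± 0.70 (at least 32.6-fold), the prostaglandin synthase gene PTGS2 at −5.44 ± 0.63 (at least 19-fold) and IL1B at −3.85 ± 0.49. Of 29 matrix genes, 3 were lower, SPARC at −4.51 ± 0.37 (at least 8.83-fold), THBS2 at −4.14 ± 0.70 and MMP2 at −3.13 ± 0.41 (at least 7.97-fold). The mesenchymal list had 2 genes lower of 20, SNAI2 at −4.76 ± 0.75 and FAP at −2.93 ± 0.44 (at least 3.66-fold), and the contractile list 1 of 18, TPM2 at −2.45 ± 0.34 (at least 1.62-fold). Of 26 genes often silenced or lost in prostate cancer, 4 were lower, DKK3 at −5.73 ± 0.73, PDLIM4 at −2.83 ± 0.51, PTGS2 and SERPINB5. Of 31 interferon-stimulated genes, 1 was lower, TRIM22 at −3.67 ± 0.43 (at least 6.44-fold). Camera passed these 7 lists and 3 more of the 20, and 0 of the 20 passed with an estimated correlation. The 3 were hypoxia and glycolysis (median −0.61), oxidative phosphorylation (median 0.59) and genes often raised in prostate cancer (median 0.69), with 0 single genes called in each. Adjusted over the list alone, 5 NF-kappaB, 8 matrix, 3 mesenchymal, 1 contractile, 4 silenced and 2 interferon genes were lower. For hypoxia 1 gene was lower that way, for the raised list 2 were higher and for oxidative phosphorylation 0 passed.

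Camera adjusted p against PrEC was 1.84e-05 for the NF-kappaB list, 3.39e-07 for matrix, 3.27e-05 for mesenchymal, 0.000362 for contractile, 1.08e-08 for silenced and 0.0264 for interferon genes. It was 0.000674 for hypoxia, 3.69e-05 for oxidative phosphorylation and 0.00989 for the raised list. In the same order, the adjusted p was 0.396, 0.0572, 0.0904, 0.0572, 0.0904, 0.616, 0.212, 0.337 and 0.212 with an estimated correlation. The junction list had a median of −0.17 but a mean of 0.26, where the test pointed up (camera adjusted p = 0.666).

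Further decreases against PrEC were found for CLCA2 at −5.35 ± 0.46 (at least 31.6-fold), the cyclin gene CCND2 at −5.23 ± 0.46 (at least 36-fold) and IGFBP7 at −4.84 ± 0.53 (at least 14.2-fold). The 6 increases were CLDN3 by 4.37 ± 0.71 (at least 5.55-fold), MACROD1 by 3.37 ± 0.46 (at least 2.98-fold), the chaperone gene CLGN by 3.16 ± 0.53 (at least 3.76-fold), MRPL46 by 2.30 ± 0.40 (at least 2.44-fold), COBL by 2.27 ± 0.38 (at least 2.55-fold) and RPL36AL by 2.05 ± 0.32. Adjusted p for these 6 ran from 0.0116 to 0.0365. Of the 6, MACROD1 alone kept its call under all 18 alternatives. CLDN3 lost it under 10, MRPL46 and COBL under 9 each, CLGN under 8 and RPL36AL under 7. Of the 25 called genes chosen by the fixed rule, 9 kept their call under every alternative that retained them: KRT14, KRT5, CLCA2, CCND2, IGFBP7, IL1B, MACROD1, MMP2 and TRIM22. The filter on the mean retained 14 of the 25, of which 4 lost their call, and KRT14, KRT5, CLCA2 and TRIM22 were not tested under it. CDH1, higher than in stroma, differed from PrEC by −0.60 ± 0.98 and did not pass (adjusted p = 0.894), nor did MKI67 at −0.40 ± 0.48 (adjusted p = 0.833). The 32 cell cycle genes had a median of 0.07 and 0 calls, with a camera adjusted p of 0.901. GSTP1 at −3.23 ± 1.13 and CAV1 at −5.41 ± 1.72 did not pass (adjusted p = 0.341 and 0.284). The remaining genes of the fixed set did not pass against PrEC: KLK3 at 4.18 ± 3.02, TMPRSS2 at 3.52 ± 2.29, HOXB13 at 3.27 ± 1.54, KLK2 at 2.86 ± 2.0, EPCAM at 1.98 ± 0.55, FOLH1 at 1.93 ± 0.96 and EZH2 at 0.69 ± 0.65. Nor did KRT18 at 0.07 ± 0.55, CDKN2A at 0.04 ± 0.83, ETV1 at −0.17 ± 0.81, CXCL8 at −0.41 ± 1.73, IL6 at −0.49 ± 0.75, KRT8 at −0.50 ± 0.65 and MYC at −0.55 ± 0.60. The same held for ACTA2 at −0.79 ± 0.32, RB1 at −1.01 ± 0.69, ZEB1 at −1.14 ± 0.77, COL1A1 at −1.90 ± 0.51 and VIM at −3.79 ± 1.56. For these 19 the adjusted p ran from 0.195 to 0.991. The count of 48 fell to 17 with a pseudocount of 1, to 15 with the filter on the mean and to 29 with only lines and PrEC in the fit. It was 24 without stromal culture 1 and 24 without stromal culture 2, 27 without CWR22Rv1 and 28 without LNCaP, against 92 without DU-145 and 79 without PC-3.

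In the overlap of these 2 comparisons, 22 genes were called in the same direction against stroma and against PrEC, and 0 in opposite directions. The 5 higher genes were CLDN3, CLGN, COBL, MACROD1 and RPL36AL. The 17 lower genes included CCND2, DKK3, FAP, IGFBP7, MMP2, PDLIM4, PTGS2, SNAI2, SPARC, THBS2, TPM2 and TRIM22. Independent lists of these sizes would share 0.398 higher and 2.6 lower genes, a value that leaves out the shared lines. In 100 simulations with unchanged groups 0 genes were shared, a value that leaves out all real effects and so gives no expected overlap for 2 lists of real calls. The same 6 lines enter both comparisons, so the 2 sets of calls are not independent, and the excess over either value is not read as a shared effect. With the lines split 3 and 3 between the comparisons, 20 splits shared a median of 7 genes and between 0 and 63. The overlap was 9 without stromal culture 1 or stromal culture 2, 14 without C42B, 13 without CWR22Rv1, 12 without LAPC4 and 12 without LNCaP, 50 without DU-145 and 41 without PC-3.

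**Figure D3:**
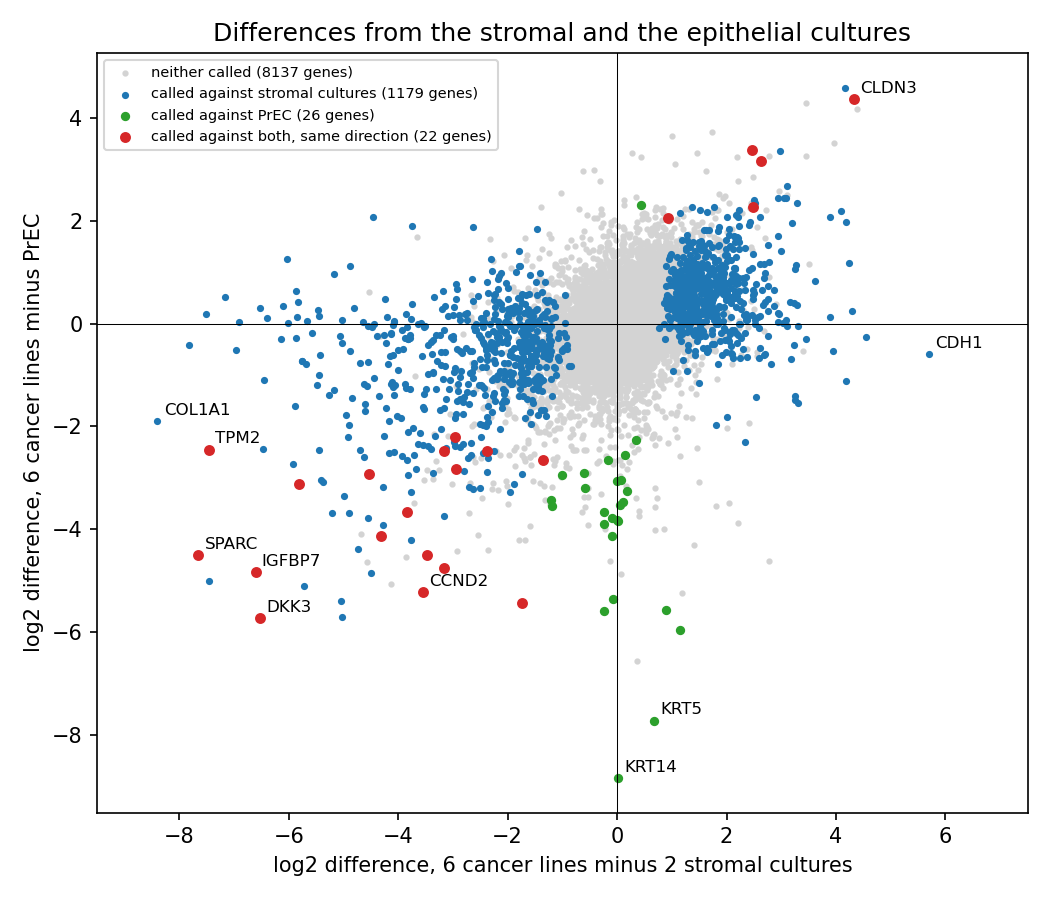
Log2 difference of each of 9364 genes between the 6 cancer lines and the 2 stromal cultures (horizontal axis) and between the lines and PrEC (vertical axis), coloured by which comparison called it at an adjusted p of 0.05. KRT14 lies at −8.85 on the vertical axis and near 0 on the horizontal axis, COL1A1 at −8.40 on the horizontal axis, and the 22 genes called against both in the same direction are red.

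The third comparison set the 2 kinds of normal cell against each other. In PrEC 15 of 29 matrix and 10 of 18 contractile genes were lower, and 7 of 20 basal and 4 of 20 junction genes higher, where the junction list had an adjusted p of 0.208 with an estimated correlation. KRT14 was higher in PrEC by 8.86 ± 0.54 (SE, n = 1 and 2 cultures), at least 191-fold, KRT5 by 8.41 ± 0.80, at least 165-fold, FGFBP1 by 7.11 ± 0.94 (at least 87.3-fold), SERPINB5 by 6.48 ± 1.10 (at least 39.5-fold) and CDH1 by 6.29 ± 1.11 (at least 29.5-fold). COL1A2 differed by −7.71 ± 0.40, at least 205-fold lower in PrEC, MYL9 by −7.69 ± 1.30 (at least 74.8-fold), COL3A1 by −7.41 ± 0.54 (at least 92.1-fold), IGFBP3 by −7.28 ± 1.36 and COL6A3 by −6.95 ± 0.74 (at least 79.4-fold). Adjusted p over these 10 genes ran from 2.65e-05 to 0.0265. In limma, 152 of 9364 genes passed, 51 higher and 101 lower in PrEC, with the spread pooled over all 3 groups. The 6 cancer lines mainly set that spread, and PrEC, a single sample, adds nothing to it. Standard errors here therefore carry differences between the lines. KLK3, at 0.20 ± 3.43, had signals of 10.9 in PrEC and a mean of 7.18 in stroma.

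Of 20 basal genes, 7 were higher in PrEC, or 18 adjusted over the list alone, with a median of 5.20. Of 20 junction genes, 4 were higher, or 9 adjusted over the list alone, including SPINT2 by 4.82 ± 0.59 (at least 22.9-fold), SPINT1 by 4.48 ± 0.57 (at least 8.6-fold) and the desmosomal gene DSP by 3.78 ± 0.54. Of 29 matrix genes, 15 were lower in PrEC, of 18 contractile genes 10, and of 20 mesenchymal genes 3, or 20, 10 and 8 adjusted over the list alone, with COL6A2 at −6.53 ± 1.23 (at least 37.8-fold), COL1A1 at −6.50 ± 0.58, TAGLN at −6.46 ± 0.44 (at least 109-fold), ACTG2 at −5.72 ± 0.52 (at least 64.5-fold), MYLK at −5.57 ± 0.39 (at least 25.9-fold), ACTA2 at −4.90 ± 0.37, PDGFRA at −4.41 ± 0.51 (at least 6.6-fold), PDGFRB at −3.95 ± 0.46 (at least 7.28-fold) and CDH11 at −3.63 ± 0.55 (at least 5.29-fold). Of 32 cell cycle genes, 1 was higher, CENPF by 3.15 ± 0.63 (at least 5.25-fold), or 14 adjusted over the list alone. Of 18 sterol genes, 1 was higher, HMGCS1 by 3.84 ± 0.69, or 9 adjusted over the list alone. SCD was higher by 3.30 ± 0.56 and GBP1 lower at −3.23 ± 0.57 (at least 2.81-fold). Among cytokine genes IL1A, IL1B and PTGS2 were higher by 5.35 ± 0.80, 3.86 ± 0.56 and 3.70 ± 0.72 and CCL2 lower at −5.40 ± 0.48 (at least 16.8-fold), in a list that did not pass (camera adjusted p = 0.996). Camera passed 7 of 20 lists, and 4 with an estimated correlation. Its adjusted p was 4.77e-19 for basal, 5.15e-11 for junction, 2.63e-33 for matrix, 1.9e-19 for contractile, 8.41e-08 for mesenchymal, 2.23e-13 for cell cycle and 3.38e-07 for sterol genes. With an estimated correlation the adjusted p was 0.0373 for basal, 0.0013 for matrix, 0.0013 for contractile and 0.0445 for mesenchymal genes, and 0.208, 0.304 and 0.224 for junction, cell cycle and sterol genes. The count of 152 was 83 without stromal culture 1 and 63 without stromal culture 2. It was 89 with a pseudocount of 1, 64 with the filter on the mean and 792 with only PrEC and stroma in the fit. In that last fit the spread within groups came from the 2 stromal cultures alone. Of the 30 called genes chosen by the fixed rule, 17 kept their call under every alternative that retained them, KRT14, KRT5, COL1A2, COL3A1 and ACTA2 among them, and CDH1 lost it without either stromal culture. The filter on the mean retained 18 of the 30, of which 1 lost its call, and KRT14, KRT5 and COL3A1 were among those not tested under it. The remaining genes of the fixed set did not pass between PrEC and stroma: KRT8 at 2.80 ± 0.73, MYC at 2.53 ± 0.68, EPCAM at 2.20 ± 0.63, EZH2 at 1.39 ± 0.74, MKI67 at 1.10 ± 0.55, GSTP1 at 0.93 ± 1.28 and RB1 at 0.73 ± 0.79. Nor did KRT18 at 0.58 ± 0.62, TMPRSS2 at 0.45 ± 2.60, ETV1 at 0.38 ± 0.91, CAV1 at 0.36 ± 1.96, KLK3 at 0.20 ± 3.43, HOXB13 at 0.18 ± 1.75 and CDKN2A at −0.15 ± 0.94. The same held for FOLH1 at −0.21 ± 1.09, KLK2 at −0.38 ± 2.27, VIM at −0.75 ± 1.77, CXCL8 at −1.78 ± 1.97, IL6 at −2.43 ± 0.85 and ZEB1 at −2.96 ± 0.87. For these 20 the adjusted p ran from 0.119 to 0.992.

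The fourth comparison set the 6 lines against the 3 normal cultures together. The lines were higher for CLDN3 by 4.34 ± 0.45 (SE, n = 6 and 3), at least 6.20-fold, with an adjusted p of 0.000944, and for EEF1A2, CENPN, EPCAM and TPD52 by 4.31 ± 0.79, 3.46 ± 0.76 (at least 5.87-fold), 3.44 ± 0.52 and 3.29 ± 0.48. Further increases were found for NPRL2 by 3.11 ± 0.43 (at least 4.62-fold), TM7SF2 by 2.98 ± 0.59 (at least 6.12-fold), FOXA1 by 2.97 ± 0.47 (at least 7.32-fold), the nucleoporin gene NUP210 by 2.88 ± 0.31 (at least 4.91-fold) and the receptor gene ERBB3 by 2.84 ± 0.51 (at least 7.06-fold). TGFBI differed by −6.65 ± 0.83, SPARC by −6.61 ± 0.60 (at least 38.4-fold), DKK3 by −6.26 ± 0.48, COL1A1 by −6.23 ± 1.18 (at least 34.8-fold), IGFBP7 by −6.02 ± 0.46 (at least 32.5-fold) and TPM2 by −5.79 ± 0.90 (at least 18.2-fold). The fibronectin gene FN1 stood at −5.51 ± 1.06, F3 (tissue factor) at −5.26 ± 0.74, CAV1 at −5.17 ± 1.09 and CCN2 at −5.13 ± 1.01. Adjusted p over these 20 genes ran from 0.000153 to 0.0281. In limma 535 of 9364 genes passed, 269 higher and 266 lower. ACTA2 at −4.05 ± 0.88, VIM at −4.29 ± 0.99 and ZEB1 at −3.12 ± 0.71 passed, though for VIM and ZEB1 single cultures of the 2 groups overlapped. CDH1 at 3.59 ± 1.26, KLK3 at 4.31 ± 1.90 and GSTP1 at −2.60 ± 0.73 did not pass (adjusted p = 0.107, 0.188 and 0.0587). The remaining genes of the fixed set did not pass against the 3 normal cultures: TMPRSS2 at 3.82 ± 1.44, HOXB13 at 3.39 ± 0.97, KLK2 at 2.61 ± 1.26, FOLH1 at 1.79 ± 0.61, EZH2 at 1.62 ± 0.48, KRT8 at 1.36 ± 0.64 and MYC at 1.14 ± 0.58. Nor did KRT18 at 0.46 ± 0.36, MKI67 at 0.34 ± 0.36, ETV1 at 0.08 ± 0.51, CDKN2A at −0.06 ± 0.52, RB1 at −0.53 ± 0.46, CXCL8 at −1.59 ± 1.13 and IL6 at −2.11 ± 0.64. The same held for KRT5 at −2.12 ± 1.53 and KRT14 at −2.94 ± 1.57. For these 16 the adjusted p ran from 0.0637 to 0.962.

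The normal group of that comparison mixed 2 cell types. Its differences and bounds are for the mean of the 3 cultures and need not hold for PrEC. From PrEC alone, COL1A1 differed by −1.90, TPM2 by −2.45, ACTA2 by −0.79 and EPCAM by 1.98. From stroma these genes differed by −8.40, −7.46, −5.69 and 4.18. For CLDN3 and DKK3 the differences were 4.37 and −5.73 from PrEC, and 4.32 and −6.53 from stroma. The count of 535 was 1204 without PrEC, 44 without stromal culture 1 and 44 without stromal culture 2. It was 222 without C42B, 273 without CWR22Rv1, 338 without LAPC4 and 187 without LNCaP, and 228 with LNCaP and C42B averaged. Of the 23 called genes chosen by the fixed rule, 8 kept their call throughout: CLDN3, NPRL2, NUP210, DKK3, F3, IGFBP7, SPARC and TGFBI.

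Each line was also described by the genes highest above all other lines, with no test, since each line was 1 array. CWR22Rv1 stood out for the protease inhibitor gene SPINK1, with a signal of 2790 against at most 32.8 elsewhere among the lines, TSPAN8 at 3150 against 62.2 and the albumin gene ALB at 989 against 13.7. The log2 excess of ALB, 4.99, became 2.27 with the mean of its probe sets. LAPC4 had CRISP3 at 2610 against 17.0, LBH at 722 against 56.6 and CALML5 at 478 against 32.1. PC-3 had S100A2 at 5120 against 132, LOXL1 at 2400 against 75.4 and S100A9 at 1400 against 58.7, and S100A2 reached 16000 in PrEC. DU-145 had UCHL1 at 4140 against 105, VIM at 4840 against 310 and SERPINA1 at 1260 against 71.4, a log2 excess of 3.84 that became 2.72 with the mean of its probe sets, and the stromal means of UCHL1 and VIM were 5320 and 7730. C42B had PAGE1 at 1420 against 75.5, RCC1 at 3740 against 497 and CSTA at 378 against 44.4. LNCaP had RLN1 at 920 against 116, the acid phosphatase gene ACP3 at 744 against 129 and PEG3 at 784 against 144. The number of genes more than 4-fold above every other line was 49 in PC-3, 38 in DU-145, 36 in CWR22Rv1, 17 in LAPC4, 11 in C42B and 6 in LNCaP, on the log2(signal + 18) scale. LNCaP and C42B are related, and each was the other's nearest neighbour among the lines.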

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

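No test of this part was chosen after a result was seen. For each of 148 genes named in the text, the 6 lines were checked for 1 line far from the others, as the gap to the nearest line over the whole range on the log2 scale. Such a line was found at 30 genes, where chance flags about 1 in 20; across all 9364 genes the share was 8.59%. The 3 genes named for each line were picked for their excess over the others, so many of them stand here by construction.

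DU-145 stood far from the other lines at 9 genes. Several were mesenchymal or epithelial markers, of which the genes named in the text hold many by rule. It was lowest for CDH1, with a gap of 0.718 of the range (signal 200, next 1100), and NPRL2 (0.629). It was highest for MYL9 (0.918; signal 257, next 10.0), DKK3 (0.905), SERPINA1 (0.798), UCHL1 (0.797), TGFBI (0.794; signal 359, next 26.6), CDKN2A (0.693) and VIM (0.690). PC-3 was highest for IL6 (0.779), S100A2 (0.775), S100A9 (0.724) and LOXL1 (0.723) and lowest for ACTA2 (0.662). LAPC4 was highest for CRISP3 (0.874), LBH (0.869) and CALML5 (0.732) and lowest for the cell cycle inhibitor gene CDKN1A (0.751; signal 34.2, next 262). CWR22Rv1 was highest for ALB (0.937), TSPAN8 (0.836), SPINK1 (0.816) and IGFBP3 (0.666). C42B was highest for KRT14 (0.815, at a dim signal of 22.6), RCC1 (0.814), CSTA (0.714) and PAGE1 (0.705), and lowest for CENPF (0.670) and EZH2 (0.650). LNCaP was highest for VWF (0.789) and RLN1 (0.664). Each value rests on 1 array per line, and no explanation was tested.

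Probe sets without a single gene name entered no comparison of genes. Of 1889 such probe sets above the array median on at least 1 array, 160, or 8.47%, passed limma between the lines and the stromal cultures, and 87 of the 160 were higher in the lines.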

How the results depend on the processing

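No test of this part was chosen after a result was seen, since every alternative was fixed before the data were examined. No called value for a named gene or list changed direction: of the values under all alternatives, 3233 kept their call and 463 lost it, and among results not called 2109 stayed so, 40 gained a call and 89 changed sign. The called genes among those named were mostly picked for large differences, many with groups that do not overlap, so a change of direction had little room. Against stroma, 1201 genes became 284 with R1881 as a covariate. Against PrEC, 48 became 17 with a pseudocount of 1, 15 with the filter on the mean and 29 with only the 2 groups. For PrEC against stroma, 152 became 89, 64 and 792 under the same 3 alternatives. The overlap of 22 became 10, 10 and 10 under them and 13 with LNCaP and C42B averaged. That averaging took 535 to 228 for all normal cultures and 91 to 43 for PC-3 and DU-145. An estimated correlation took the lists from 14 to 3, 10 to 0 and 7 to 4. Leaving out 1 sample gave 246 to 1332 genes against stroma, 24 to 92 against PrEC, 63 to 182 for PrEC against stroma and 44 to 1204 for all normal cultures. It gave 35 to 114 for PC-3 and DU-145 and 9 to 50 for the overlap, with lists at 14 to 15, 9 to 12 and 7 to 8. A lone sample left in a group was assumed to vary like the other groups. Averaging, the filter on the mean and samples left out reduce genes or samples, yet some counts rose with a sample left out. The cause of these shifts was not tested. Called genes that kept their call under every alternative that retained them were 27 of 68 against stroma, 9 of 25 against PrEC, 17 of 30 for PrEC against stroma, 8 of 23 for all normal cultures and 10 of 24 for PC-3 and DU-145; the filter on the mean retained 53, 14, 18, 21 and 19 of these. Among single lines, the mean of probe sets took ALB from 4.99 to 2.27 and SERPINA1 from 3.84 to 2.72. The median difference over all genes went from 0.13 to −0.05 for PrEC against stroma with median centring. No paired analysis was possible because replicate numbers follow accession order and pair no cultures. Signal over background limits dim genes, whose changes the pseudocount shrinks.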

Other observations

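The split counts of this part were fixed before the data were examined, and so was the test of R1881; the tests of medium, array brightness, sharing with basal cells and the androgen list were chosen after the results were seen. PC-3 and DU-145 were set against the other 4 lines, a split taken from textbook knowledge of androgen-insensitive lines and not from the labels. In these 2 lines the kinase gene AXL was higher by 5.78 ± 0.67 (at least 28.6-fold) on the log2 scale (SE, n = 2 and 4 lines), the protease gene PLAU by 5.60 ± 0.31, at least 45.4-fold, S100A6 by 5.43 ± 0.64, the keratin gene KRT7 by 5.08 ± 0.42 (at least 19.3-fold) and FHL2 by 4.75 ± 0.40 (at least 13-fold). Adjusted p over these 5 ran from 0.000502 to 0.00735. In limma 91 of 9364 genes passed, 71 higher and 20 lower. The laminin gene LAMB3 was higher by 4.22 ± 0.46, the actin-binding gene ACTN1 by 2.47 ± 0.39 and the proteasome gene PSMB8 by 2.46 ± 0.34 (at least 1.68-fold). Of 26 genes often silenced or lost in prostate cancer 5 were higher, among them S100A6, ANXA1 by 4.62 ± 0.46, CAV1 by 4.25 ± 0.40 (at least 9.14-fold) and CAV2 by 3.0 ± 0.42 (at least 5.99-fold), or 7 adjusted over the list alone. Of 22 NF-kappaB genes 3 were higher, CXCL8 by 4.12 ± 0.43 (at least 6.04-fold), CXCL2 by 2.86 ± 0.35 (at least 2.32-fold) and LIF by 2.38 ± 0.40 (at least 3.13-fold), or 9 adjusted over the list alone; CXCL2 was read from a probe set that can cross-hybridise. Camera adjusted p was 7.83e-06 and 6.97e-10 for these lists, and adjusted p = 0.115 and 0.0776 with an estimated correlation. In all, camera passed 14 of 20 lists for these 2 lines, 0 of them with an estimated correlation. LAMB3, ACTN1 and PSMB8 were each the only gene called in their list, of 20 basal, 18 contractile and 16 class I genes. Camera adjusted p for these lists was 1.61e-05, 0.0681 and 0.00106, and adjusted p = 0.115, 0.236 and 0.228 with an estimated correlation. Adjusted over the list alone, 1, 3 and 4 genes were higher.

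Of 12 cancer-testis antigens 3 were lower in the same 2 lines, also 3 adjusted over the list alone, with a camera adjusted p of 5.04e-06, and an adjusted p of 0.0776 with an estimated correlation. MAGEA6 differed by −5.51 ± 0.34 (at least 28.6-fold), MAGEA12 by −4.18 ± 0.33 (at least 12.9-fold) and MAGEA1 by −3.93 ± 0.59 (at least 5.2-fold), the 3 called, all on cross-hybridising probe sets, which cannot tell these related genes apart with certainty. The selenium genes SELENOP and SELENBP1 stood at −4.0 ± 0.35 (at least 8.07-fold) and −3.45 ± 0.40, and MAZ at −2.67 ± 0.41 (at least 3.96-fold). The lipid synthesis genes TM7SF2 and ACACA stood at −2.08 ± 0.30 and −1.81 ± 0.29, each the only gene called, of 18 sterol and 14 fatty acid genes, or 1 and 2 adjusted over the list alone. Camera adjusted p was 0.0169 and 0.00391 for these lists, and adjusted p = 0.495 and 0.118 with an estimated correlation. The homeobox gene HOXB13 stood at −3.54 ± 0.59 (adjusted p = 0.0349) and the protease gene TMPRSS2 at −5.18 ± 0.94 (at least 18.1-fold, adjusted p = 0.0496). KLK3 at −6.56 ± 1.39 and KLK2 at −4.43 ± 0.86 did not pass, with adjusted p of 0.0796 and 0.0585, nor did FOLH1 at −2.01 ± 0.48, CDH1 at −1.85 ± 0.57 or VIM at 2.64 ± 1.03 (adjusted p = 0.118, 0.213 and 0.325). The remaining genes of the fixed set did not pass: CDKN2A at 1.35 ± 0.51, IL6 at 1.25 ± 0.46, GSTP1 at 1.11 ± 0.92, KRT8 at 1.03 ± 0.40, ZEB1 at 0.95 ± 0.58, EPCAM at 0.76 ± 0.39 and COL1A1 at 0.70 ± 0.43. Nor did RB1 at 0.62 ± 0.55, EZH2 at 0.57 ± 0.53, MKI67 at 0.33 ± 0.41, KRT18 at 0.24 ± 0.38, ETV1 at 0.19 ± 0.70, KRT5 at 0.16 ± 0.64 and MYC at 0.15 ± 0.52. The same held for ACTA2 at −0.20 ± 0.29 and KRT14 at −0.27 ± 0.41. For these 16 the adjusted p ran from 0.299 to 0.948. The count of 91 was 53 without DU-145, 57 without PC-3, 35 without C42B and 39 without LNCaP. Of the 24 called genes chosen by the fixed rule, 10 kept their call under every alternative that retained them, PLAU, KRT7, FHL2, ANXA1, CAV1, CXCL8, MAGEA6, MAGEA12, SELENOP and SELENBP1. The filter on the mean retained 19 of the 24, and CXCL8 was not tested under it.

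The first pattern weighed was the set of 1201 genes called between the lines and stroma, where R1881 and medium differ along with the cell type. Over 1063 genes picked without LAPC4, LAPC4, which was grown with R1881, showed a median of 0.942 of the difference shown by the other 5 lines (95% bootstrap interval 0.925 to 0.962). It lay nearer those lines than stroma at 950 genes, or 89.4%. R1881 as a general cause does not account for that, but the test rests on 1 line, and a response limited to stromal cells stays untested. PrEC, in RPMI by its label, a medium unusual for such cells and not checked here, showed a median of 0.677 of the difference over the 1201 genes (0.659 to 0.709), so, if the label holds, a part could come from medium, from cell type or from both, and nothing here tells them apart.

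The second pattern was the set of 535 genes called between the lines and all 3 normal cultures. Of the 84 ways to split the 9 arrays into 6 and 3, only 1, the real one, called that many, and the highest count of any other split was 36. This excludes chance only if the 9 arrays are taken as interchangeable, and the stromal cultures, at a correlation of 0.93, and LNCaP and C42B are not. Among the 7 splits with both stromal cultures in the group of 3, the real one was the highest and the next called 36, and 7 splits are too few for a share under 0.05. The split does not tell cancer from the culture conditions and cell types that go with it.

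The third pattern was the set of 91 genes between PC-3 and DU-145 and the other lines. Of 15 splits 1, the real one, called that many, and the next called 7, and 15 splits are too few for a share under 0.05. Array brightness was weighed by rescaling. With the arrays centred on equal spike-in signal, 79 of the 91 stayed called with the same sign. So did 87 with quantile normalization and 85 with median centring. These checks could hardly come out otherwise, so by themselves they decide nothing about brightness. The spike-in means of DU-145 and PC-3, 9.40 and 9.63, lay within the 9.16 to 9.90 of the other lines. Centring therefore moved the difference between the groups little, and the authors had already scaled the arrays to the same trimmed mean. With the spike-in signal as a covariate, a median of 0.984 of the difference remained (0.975 to 0.993) and all 91 kept their sign, though 55 kept their call. That estimate meets the same limit and leans on LAPC4, whose spike-in signal was the lowest. A uniform shift in brightness would move the genes in the same direction. The median difference over all genes was −0.0189, and of the 91 genes 71 were higher and 20 lower. These values argue against a uniform shift for this set, and an uneven effect of brightness stays open. Over 83 higher genes picked without CWR22Rv1, PrEC exceeded CWR22Rv1 by a median of 2.25 and stroma by 1.97, where the 95th percentiles of random sets matched on level were 0.111 and 0.0147. The rule that stroma must not pass its own percentile was added after this result was seen, and by the earlier rule the test would have counted for sharing. The brightness test replaced one on the range of the spike-in signals, which turned on LAPC4 alone. The genes were picked as low in C42B, LAPC4 and LNCaP, which correlate with CWR22Rv1 at 0.83 to 0.85, so the test decides nothing about sharing with basal cells. The androgen-response list had a median of −0.788 with a camera adjusted p of 0.000203, and an adjusted p of 0.228 with an estimated correlation. This leaves the hypothesis of lower androgen response undecided. LAPC4 was grown with R1881, and PC-3 and DU-145 without it, so androgen in the medium differed in part along this split.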
